A study of Homo sapiens with 7 samples.

How the data were processed

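Hi-C was measured in 7 human libraries, each deposited as its own file. Per the labels' protocols, cells were grown in DMEM, trypsinised and counted, and chromatin was cut with MboI, marked with biotin at the filled-in ends, ligated with T4 ligase, fragmented with Tn5 transposase, captured on streptavidin and amplified by PCR. Per the submitters' processing notes, cutadapt and HiC-Pro were used with the human build hg19; their versions and settings are not given in the sources used here. The deposited signal is a list of contact values between pairs of 40 kb bins after ICE balancing, an iterative correction that scales every bin of a library to the same total, per the file names. Balancing removes differences in total coverage between bins, so copy number cannot be read from the bin totals of a balanced map. Whether copy number still affects single balanced contacts was not tested. Intervals are given in hg19 Mb, with bins numbered over chromosomes 1 to 22, X, Y and M. At 22 of 22 starts of chromosomes tested, few reads spanned the position (median 2, against 2984 elsewhere), which checked that numbering.

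Each balanced value equals a whole number of read pairs times a factor for each of its 2 bins. Those factors were estimated from the file, and the read pairs recovered lay within 0.0129 of a whole number in every library, where 0.01 had been set as the tolerance. On a simulated library the recovered read pairs matched the true ones in 100% of entries. A total of 69659 of 75918 bins on chromosomes 1 to 22 and X were listed in every library and were used. Chromosomes Y and M stayed out of the comparisons. The precision of every value is limited by the read pairs behind it, and intervals cover counting error only, since PCR copies of a molecule are not independent.

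The compartment score of a 400 kb bin was the log2 ratio of its mean observed over expected contact with A bins to that with B bins of its chromosome, scaled to mean 0 and SD 1 in each library. A and B came from the eigenvector of the pooled map that best matched the pattern of contacts between chromosomes, with chromosome 19 set to lie in A more than chromosome 18. Compartment strength was the mean observed over expected contact of A with A and B with B, divided by that of A with B, over the outer 20% of bins at each end. The insulation score was the log2 of the mean contact in a 480 kb square beside the diagonal over the chromosome's mean, taken at 3316 boundaries of the pooled map, where a low value means few contacts across the boundary. Boundary depth was that score minus the score 400 kb away. Relative coverage was the log2 of recovered read pairs per 1 Mb bin, centred on each library's median. Contacts between chromosomes were read as log2 observed over expected, with a pseudocount of 0.5, for the 1000 pairs of 1 Mb bins with the highest mean among 3710108 pairs. The long-range share was the percent of all intrachromosomal contacts, those within a bin included, at 1 Mb or more. The decay slope was fitted to log10 contact against log10 distance from 0.4 to 10 Mb. Map similarity was a stratum-adjusted correlation of 400 kb maps up to 10 Mb. Contact within the fixed chromosome lists was the mean log2 observed over expected between the chromosomes of a list, and chromosome ends and centromere flanks took in 5 Mb.

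The cell lines were compared as 4 HEK293T against 3 HEK293 libraries, and inputs as 1 HEK293 library of 10000 cells against 2 of 1000 cells in a fit with 3 groups. Tests across bins, boundaries or pairs used limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. Coverage calls also needed a difference of 0.3. For contacts between chromosomes limma found no variation of the spread between pairs, so all pairs share an SE of 0.36. Single values per library were compared by a two-sided exact permutation test over 35 splits, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over 12 measures. The lone library of 10000 cells is assumed to vary like the other groups, which its lower depth does not bear out, and the single values were not tested between inputs. On simulated data with 200 shifted members, a shift of 0.6 was recovered for 41.8% of members among 7016 compartment bins, 95.5% among 3316 boundaries, 97% among 2816 coverage bins and 8.96% among 1000 pairs. Other computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

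Groups, tests, most alternatives and the naming rule were set before the data were examined. The rule takes, for each limma result, the 10 called members with the largest difference in each direction, merges neighbours, and adds chromosomes or arms with over 50% of bins called in one direction. A merged region carries the values of its strongest member, which need not hold over the whole interval. Giving values for only the first 4 regions per direction between lines, and 3 between inputs, was decided after the data were seen, and the rest are summarised. The share of contacts within a bin, the long-range share without those contacts, the gene-poor value without the pair of chromosomes 13 and 18, the removal of the coverage trend, thinning to equal contacts between bins, subtraction of the interchromosomal background and the scan for contacts raised in a single line were also chosen after the data were seen. The other alternatives were unbalanced reads, equal depth, a stricter bin filter, other bin sizes, windows, distances, pseudocount and centring, the input given in the protocol text, the replicate number as a block and leaving out each library. An annotation of hg19 was not used here, so regions carry coordinates and no genes.

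The title and characteristics of HEK293 1000-cell replicate 1 give 1000 cells, while the protocol text gives 10000 cells to the sample name carried by that library's file. The title was followed. Nothing in the labels says that libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The prefixes of the sample names put all HEK293T libraries in a batch, both HEK293 1000-cell libraries in another and the HEK293 10000-cell library in its own. Each batch therefore holds a single group, no value within a batch can be had, and batch cannot be told apart from cell line or input. A chi-square of 1 Mb coverage per degree of freedom lay between 1.61 and 21.6 for pairs within a group. HEK293T replicate 1 stood apart, at 10.2 to 13.0 with replicates 2 to 4, which lay at 1.61 to 1.88 with each other. HEK293 1000-cell replicate 1 stood at 21.6 with replicate 2 and at 16.0 with the 10000-cell library, though the measure grows with depth, and replicate 2 stood at 56.1 with that library. In map similarity replicate 1 was nearer to replicate 2 (0.745) than to that library (0.618). No library was treated as a copy of another.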

Results

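Hi-C joins DNA ends that lie near each other in the nucleus, so the read pairs linking a pair of genomic bins measure how often these were in contact. HEK293 is a human embryonic kidney line transformed with adenovirus DNA, and HEK293T is a derivative that carries the SV40 large T antigen. Both are aneuploid. The series concerns building such libraries from few cells, with 4 HEK293T libraries of 1000 cells, 2 HEK293 libraries of 1000 cells and 1 HEK293 library of 10000 cells. The HEK293T libraries held 32562715, 43110917, 33761522 and 41425414 read pairs on chromosomes 1 to 22 and X. The HEK293 libraries held 29152007 and 30980250 from 1000 cells and 19387641 from 10000 cells. Intrachromosomal pairs between different 40 kb bins numbered from 19383553 to 26033874 in HEK293T. In HEK293 they numbered 15037009 and 16010626 from 1000 cells and 5845581 from 10000 cells. The 95% Wilson intervals of the intrachromosomal and within-bin shares of read pairs reached at most 0.0223 percentage points either way in any library.

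The first comparison asked how chromosome folding differed between HEK293T and HEK293. Regions of chromosome 11 and of chromosome 13 differed in compartment score between the lines, where each score is relative to its library's mean. In the strongest bin of chromosome 11, 112.4 to 113.2 Mb, the score was -0.51 ± 0.06 (SD, n = 4) in HEK293T, below the mean, toward the gene-poor B compartment. In HEK293 the score was 0.78 ± 0.06 (SD, n = 3), above the mean, toward the gene-rich A compartment. Chromosome 13 at 19.6 to 20 Mb went the other way, with 0.76 ± 0.12 in HEK293T and -0.44 ± 0.09 in HEK293. That bin begins 0.4 Mb beyond the stretch without listed contacts that ends at 19.2 Mb. Chromosome 13 was also the only chromosome whose compartment vector correlated negatively with read coverage (-0.518). Its match to the pattern of contacts between chromosomes (0.831) was the lowest, so A and B are less certain there. In all, 943 of 7016 bins differed, 429 higher and 514 lower in HEK293T.

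Beside the first region of chromosome 11, whose strongest bin differed by -1.29 ± 0.11 (SE, limma adjusted p = 2.41e-05), other intervals of the arm were lower in HEK293T. The difference was -1.21 ± 0.12 in the strongest bin from 110.4 to 111.2 Mb and -1.06 ± 0.18 from 115.6 to 116 Mb. Chromosome 1 at 56 to 56.4 Mb differed by -1.09 ± 0.12. The bin of chromosome 13 differed by 1.2 ± 0.12 (limma adjusted p = 8.61e-05). Chromosome 18 at 62.8 to 63.2 Mb, chromosome 5 at 46 to 46.4 Mb and chromosome 21 at 22.4 to 22.8 Mb were higher in HEK293T by 0.94 ± 0.19, 0.93 ± 0.26 and 0.89 ± 0.14, though all 3 had negative scores in both lines. The interval of chromosome 5 borders the stretch without listed contacts that begins at 46.4 Mb. The 10 regions named as higher spanned 0.80 to 1.2 and the 7 named as lower -0.99 to -1.29, with adjusted p up to 0.0283. In all of them each HEK293T library lay beyond each HEK293 library. Here and below such separation is partly built in, as named regions were picked by their difference in these same libraries.

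Of the 3371 bins in A, 118 were higher and 175 lower in HEK293T, and of the 3645 bins in B, 311 were higher and 339 lower. The mean score had opposite signs in the 2 lines in 133 called bins, of which 116 had the lower score in HEK293T. As scores are centred per library, these signs do not count changes of compartment. The largest shares of called bins were on 4 chromosomes. Chromosome 17 had 32 bins higher and 48 lower among 194, chromosome 16 had 19 higher and 60 lower among 194, chromosome 19 had 11 higher and 39 lower among 139, and chromosome 21 had 22 higher and 3 lower among 88. Thinning to equal numbers of contacts between bins left 32 calls. They included chromosome 13 at 19.6 Mb, chromosome 1 at 56 Mb and the 3 regions of chromosome 11, but not those of chromosomes 5, 18 and 21. Equal depth left 406 calls, a stricter bin filter 413, and leaving out HEK293T replicate 2, 3 or 4 left 590, 608 or 558. Leaving out HEK293 1000-cell replicate 2 brought the difference at chromosome 5, 46 Mb, to 0.46 and ended its call, as did leaving out HEK293T replicate 1, 2 or 3, at 0.88 to 0.92.

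Insulation differed between the lines at 132 of 3316 boundaries, 67 with more and 65 with fewer contacts across them in HEK293T. The boundary at chromosome 21, 22.32 Mb, was deeper in HEK293T, with a score of -1.03 ± 0.10 (SD, n = 4) against -0.31 ± 0.10 (SD, n = 3). The difference was -0.71 ± 0.07 (SE, limma adjusted p = 4.16e-05). Chromosome 2 at 236.64 Mb was shallower in HEK293T, at -0.25 ± 0.03 against -0.81 ± 0.09, a difference of 0.56 ± 0.06 (SE, limma adjusted p = 9.82e-05). Scores were higher in HEK293T at chromosome 1, 1.24 Mb, by 0.48 ± 0.08, at chromosome 3, 49.72 Mb, by 0.44 ± 0.10 and at chromosome 1, 1.52 Mb, by 0.43 ± 0.08. Differences were -0.50 ± 0.08 at chromosome 2, 213.44 Mb, -0.48 ± 0.11 at chromosome 18, 41.12 Mb, and -0.43 ± 0.11 at chromosome 2, 156.16 Mb. The 10 named in each direction spanned 0.36 to 0.56 and -0.38 to -0.71, with adjusted p up to 0.0436. Each HEK293T library lay beyond each HEK293 library at all of them.

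The HEK293 mean at some of these boundaries was set apart by the 10000-cell library, as at chromosome 18, 41.12 Mb, with 0.00 against -0.60 from 1000 cells, and at chromosome 3, 49.72 Mb, with -1.2 against -0.70. Reads without balancing gave 2055 calls and turned the direction at 6 of the 8 boundaries given with values, such as 0.19 at chromosome 21, 22.32 Mb. Equal contacts between bins left 6 calls, equal depth 40, an 800 kb square 254 and libraries of matched input 211. Leaving out HEK293T replicates 1 to 4 left 24, 12, 19 and 14, while leaving out HEK293 1000-cell replicate 2 gave 199. Without the 10000-cell library the differences were 0.27 at chromosome 3, 49.72 Mb, -0.28 at chromosome 18, 41.12 Mb, and -0.27 at chromosome 2, 156.16 Mb, where the call ended. The calls at those 3 boundaries also ended when any HEK293T library was left out (0.42 to 0.45, -0.44 to -0.52 and -0.33 to -0.47), and that at chromosome 1, 1.52 Mb, without HEK293T replicate 2 (0.38).

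Relative coverage, which follows DNA copy number as well as how readily chromatin is cut and ligated, differed over much of the genome, with 677 bins of 1 Mb higher and 563 lower in HEK293T among 2816. On chromosome 1 at 109 to 111 Mb the strongest bin stood at 0.28 ± 0.01 (SD, n = 4) on the log2 scale in HEK293T and 1.68 ± 0.05 (SD, n = 3) in HEK293. The difference was -1.40 ± 0.03 (SE, limma adjusted p = 1.1e-07). Coverage on chromosome 1 was also lower in HEK293T at 1 to 2 Mb, by a difference of -1.08 ± 0.10. In the strongest bin of 16 to 18 Mb the difference was -1.07 ± 0.06, and at 11 to 12 Mb -0.99 ± 0.07. Coverage was higher in HEK293T on chromosome 21 at 24 to 25 Mb by 0.99 ± 0.03 and in the strongest bin of 20 to 23 Mb by 0.98 ± 0.04. It was also higher on chromosome 18 at 27 to 28 Mb by 0.90 ± 0.04 and on chromosome 13 at 63 to 64 Mb by 0.90 ± 0.05. The 8 regions named in each direction spanned 0.87 to 0.99 and -0.94 to -1.40, with adjusted p up to 0.000239. The libraries of the lines did not overlap in any.

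Over 50% of bins were lower in HEK293T on chromosomes 1 (59.6%), 19 (75%) and 22 (70.6%) and on the arms 16p (64.7%), 17q (53.6%) and 20q (58.8%). They were higher on 4q (50.7%) and Xq (51.6%). The difference ran along the compartments, with a correlation across 1 Mb bins, which are not independent, of -0.81 with the compartment vector. With the trend of each library's deviation from the midpoint of the lines on that vector removed there were 366 calls, of which 226 had been called in the same direction before and 140 had not been called. No chromosome or arm then had over 50% of bins called in a direction. The strongest bins of the 8 regions given with values stayed called, at -0.93 for chromosome 1, 109 to 111 Mb, and 0.66 for chromosome 21, 24 to 25 Mb.

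**Figure D1:**
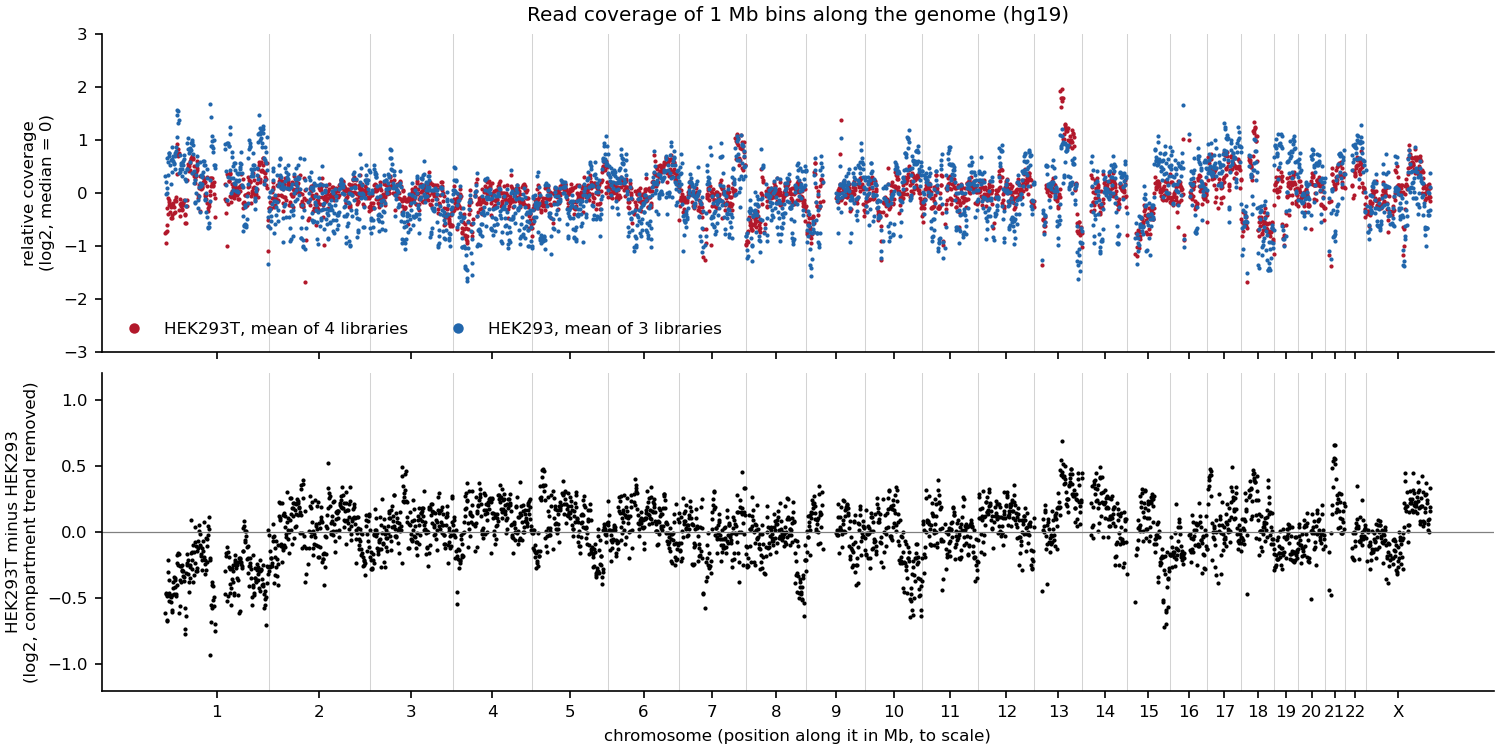
The upper panel plots the mean log2 relative coverage of each 1 Mb bin along chromosomes 1 to 22 and X for the 4 HEK293T and the 3 HEK293 libraries, and the lower panel plots the difference, HEK293T minus HEK293, after the trend on the compartment vector was removed. The strongest bin of chromosome 1 at 109 to 111 Mb, at -0.93 in the lower panel, and chromosome 21 at 24 to 25 Mb, at 0.66, stand out from the bins around 0.

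Among the 1000 pairs of 1 Mb bins with the strongest contact between chromosomes, 52 differed between the lines, 30 higher and 22 lower in HEK293T. Of the higher pairs 27 lay in clusters of at least 5 tested pairs, and of the lower pairs 0 did. Contact between chromosome 9 at 82 to 83 Mb and chromosome 18 at 77 to 78 Mb was far higher in HEK293T. Its log2 observed over expected was 6.25 ± 0.37 (SD, n = 4) against 0.58 ± 0.85 (SD, n = 3) in HEK293. The difference was 5.68 ± 0.36 (SE, limma adjusted p = 1.2e-50). That p rests on the SE shared by all 1000 pairs, not on the spread of this pair's own libraries. Contact between chromosomes 1 and 4 was higher in HEK293T at 58 to 59 Mb with 11 to 12 Mb, by 1.69. In the strongest pair of 57 to 59 Mb with 9 to 10 Mb it was higher by 1.56. Contact between chromosomes 7 and 18 was higher in the strongest pair of 144 to 146 Mb with 34 to 37 Mb, by 1.55. Among pairs outside such clusters, values were lower in HEK293T for chromosome 1 at 224 to 225 Mb with chromosome 10 at 38 to 39 Mb (-2.20) and chromosome 1 at 145 to 146 Mb with chromosome 12 at 93 to 94 Mb (-1.82). They were also lower for chromosome 1 at 219 to 220 Mb with chromosome 6 at 66 to 67 Mb (-1.70) and chromosome 1 at 83 to 84 Mb with chromosome 7 at 76 to 77 Mb (-1.63).

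The 7 regions named as higher spanned 1.33 to 5.68 and the 10 named as lower -1.47 to -2.20, with limma adjusted p up to 0.0107. There was no overlap between the libraries of the lines. The pair of chromosomes 1 and 10 had an SD of 1.67 within HEK293T yet the common SE of 0.36, and its call ended at equal depth and with an expected value per chromosome pair. Without HEK293T replicate 1 its difference was -1.38. Reads without balancing gave 426 calls, of which 357 were higher in HEK293T, and a pseudocount of 1 gave 82, of which 62 were. An expected value per chromosome pair gave 5 higher and 12 lower, and matched input 31 higher and 48 lower, which turned the balance. A stricter bin filter left 884 pairs, without the pair of chromosomes 9 and 18 and the 4 lower ones above, and gave 27 higher and 1 lower. Leaving out HEK293T replicate 1, 2 or 4 or HEK293 1000-cell replicate 2 gave 25, 16, 22 or 93.

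**Figure D2:**
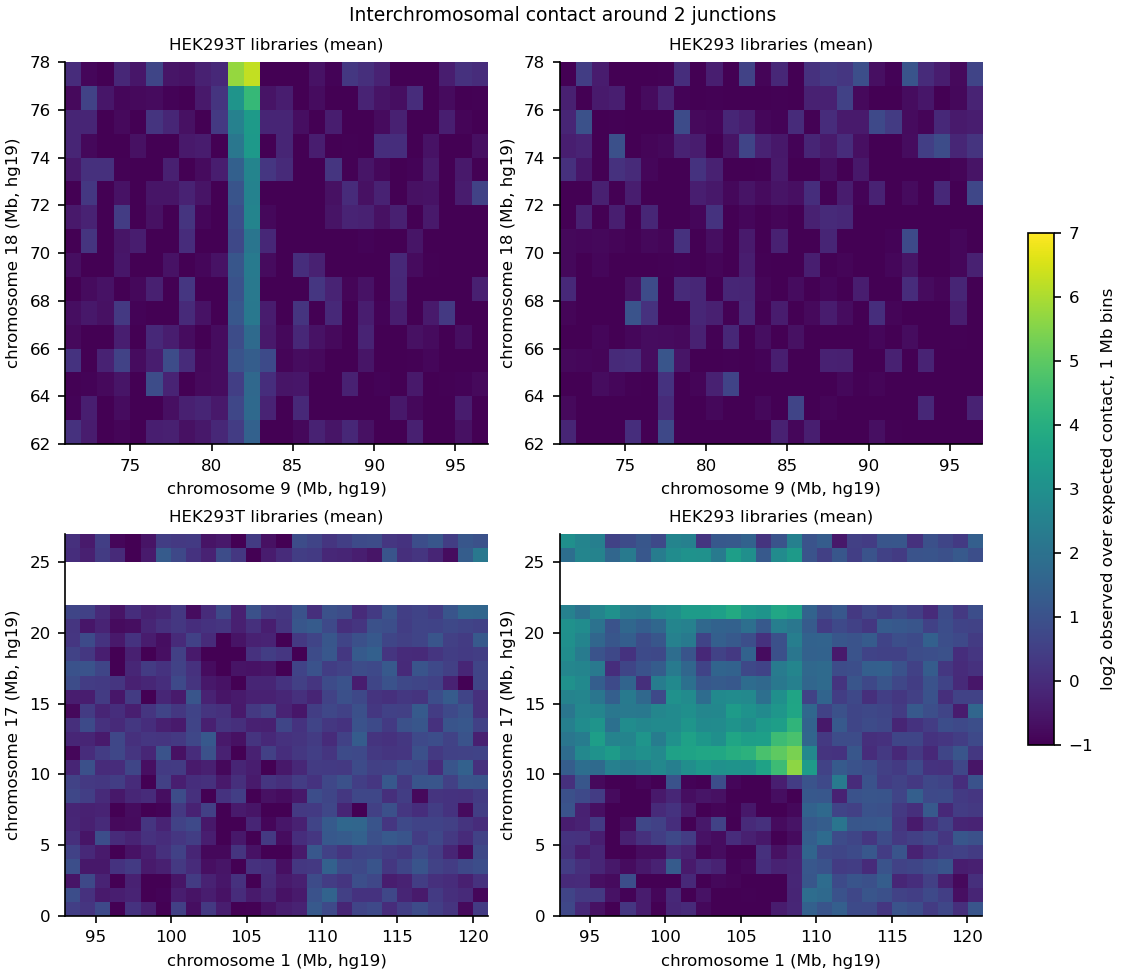
Each panel maps the mean log2 observed over expected contact between 1 Mb bins of a chromosome pair, with positions in Mb on both axes, for HEK293T (n = 4) and HEK293 (n = 3), and values under the colour scale take its lowest colour. Contact between chromosome 9 and the end of chromosome 18 reaches 6.25 in HEK293T against 0.58 in HEK293, where the 10000-cell library stood at 1.56, and contact of chromosome 1 at 108 to 109 Mb with chromosome 17 at 11 to 12 Mb reaches 5.39 in HEK293 against 0.30 in HEK293T.

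Summed over the genome, every HEK293T map had a lower share of contacts within a bin than every HEK293 map, though no measure passed the adjustment over 12 tests. The share of intrachromosomal contacts at 1 Mb or more was 28.5% ± 2.23 (SD, n = 4) in HEK293T and 20.8% ± 3.13 (SD, n = 3) in HEK293, higher in 4 of 4 HEK293T libraries (exact permutation p = 0.0286, adjusted p = 0.0686). That order held only with contacts inside a bin in the denominator. Without them the difference turned to -1.54 percentage points (exact permutation p = 0.60), with 33.1, 39.1, 40.5 and 37.5% in HEK293T against 36.7, 36.9 and 43.8% in HEK293. Contacts within a 40 kb bin made up 19.7% ± 0.558 against 38.7% ± 9.33 of all contacts, lower in 4 of 4 HEK293T libraries (exact permutation p = 0.0286, adjusted p = 0.0686). Compartment strength was 2.81 ± 0.329 in HEK293T and 3.97 ± 0.684 in HEK293 (exact permutation p = 0.0571, adjusted p = 0.098), and without balancing the difference was -1.30 (exact permutation p = 0.0286).

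The intrachromosomal share was 81.5% ± 3.35 in HEK293T and 84.8% ± 3.2 in HEK293 (exact permutation p = 0.229), and without contacts inside a bin the difference turned to 2.65 percentage points. The decay slope was -1.27 ± 0.06 against -1.27 ± 0.05 (exact permutation p = 0.886) and the boundary depth -0.64 ± 0.01 against -0.63 ± 0.01 (exact permutation p = 0.229), a difference of -0.0148 that was -0.0262 without balancing (exact permutation p = 0.0286). Contact among the small gene-rich chromosomes 16, 17, 19, 20, 21 and 22 was 0.67 ± 0.05 against 0.66 ± 0.10 (exact permutation p = 0.771), and without chromosome 21 the difference turned to -0.0035. The acrocentric chromosomes 13, 14, 15, 21 and 22 stood at 0.24 ± 0.01 against 0.21 ± 0.01 and the gene-poor chromosomes 4, 13, 18 and X at 0.10 ± 0.02 against 0.17 ± 0.00. Each had an exact permutation p of 0.0286 and an adjusted p of 0.0686, with 4 of 4 HEK293T libraries beyond every HEK293 library. The gene-poor value was above 0 only through the pair of chromosomes 13 and 18, at 1.24 ± 0.09 against 1.31 ± 0.24. The other 5 pairs averaged -0.13 ± 0.03 against -0.06 ± 0.05 (exact permutation p = 0.0571), with 3 of 4 HEK293T libraries below every HEK293 library. Chromosome ends stood at 1.2 ± 0.12 against 1.29 ± 0.21 (exact permutation p = 0.486) and centromere flanks at 0.69 ± 0.10 against 0.49 ± 0.11 (exact permutation p = 0.0571).

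**Figure D3:**
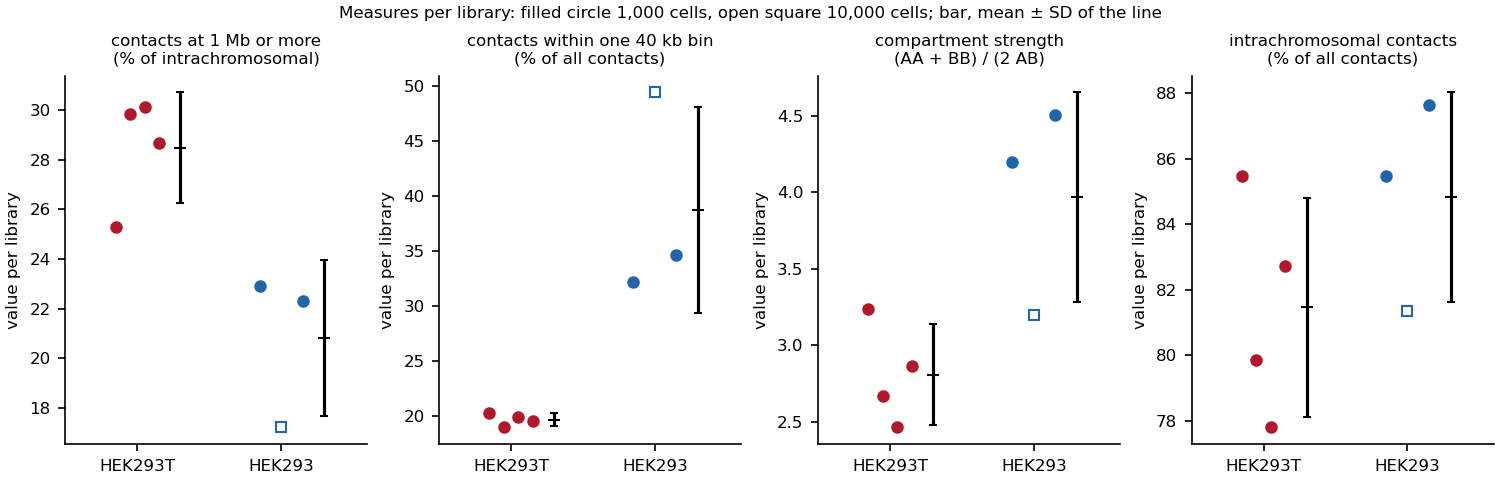
The 4 panels plot the long-range share and the within-bin share in percent, the compartment strength and the intrachromosomal share in percent of each library. Filled circles mark 1000 cells, an open square 10000 cells and bars the mean ± SD of each line. The HEK293T libraries lie between 25.3 and 30.1% in long-range share, all above the HEK293 libraries, and between 18.95 and 20.3% in within-bin share, all below them.

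On average, maps of the same line resembled each other more than maps of different lines. The mean similarity was 0.735 within lines and 0.677 between lines over 21 pairs of libraries, a difference of 0.0585 (exact permutation p = 0.0286, adjusted p = 0.0686). Pairs of HEK293T libraries ranged from 0.746 to 0.797, the 2 HEK293 libraries of 1000 cells reached 0.745, and HEK293T with HEK293 at 1000 cells ranged from 0.703 to 0.731. The HEK293 library of 10000 cells stood apart from its own line, at 0.618 and 0.627 with the 1000-cell libraries, and from HEK293T, at 0.588 to 0.603. With that library left out the difference was 0.0496 (exact permutation p = 0.0667, the smallest that design allows).

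The second comparison asked what the number of cells changed in HEK293 maps. The library from 10000 cells had the fewest read pairs and the highest share of contacts within a bin, 49.4% against 32.1% and 34.6% from 1000 cells. Its long-range share was 17.2% against 22.9% and 22.3%, and with contacts inside a bin left out it turned to 43.8% against 36.7% and 36.9%. Its intrachromosomal share was 81.3% against 85.5% and 87.6%, and with contacts inside a bin left out 63.1% against 78.6% and 81.1%. Its compartment strength was 3.2 against 4.20 and 4.51, and its boundary depth -0.61 against -0.64 and -0.64. Its decay slope was -1.21 against -1.29 and -1.30, and contact among the small gene-rich chromosomes was 0.56 against 0.66 and 0.75. With 1 library of the larger input these values were not tested. The limma calls below assume that this library varies like the other groups. Its 5845581 pairs between bins, against at least 15037009 in any other library, do not bear that out for compartments and boundaries. The calls therefore set a single library apart from the others, and do not show an effect of input.

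**Figure D4:**
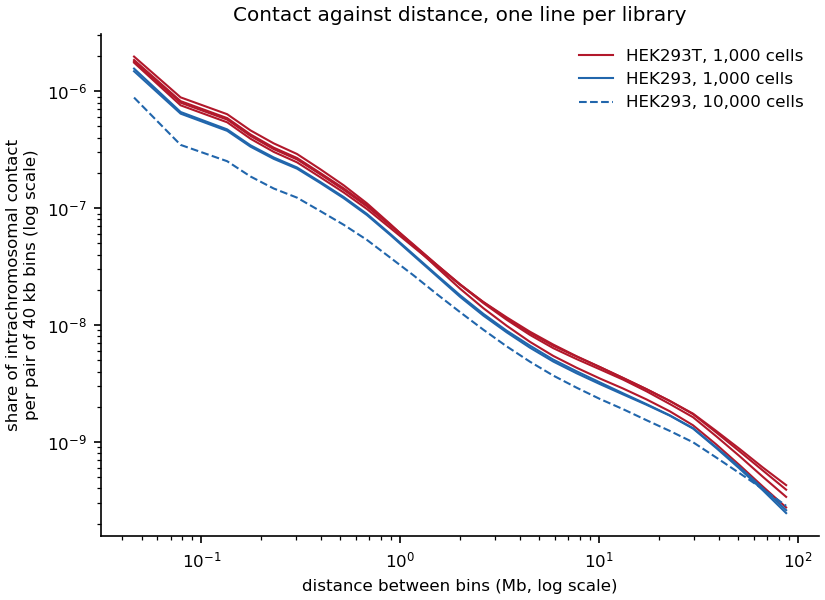
Each line plots, for a library, the share of intrachromosomal contact per pair of 40 kb bins against their distance in Mb, both on log axes, with colours for the groups. The curves run nearly parallel, with slopes from 0.4 to 10 Mb between -1.35 and -1.21, and the 10000-cell library lies lowest over most of the range, with 49.4% of its contacts within a bin.

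For insulation limma called 626 of 3316 boundaries, 310 higher and 316 lower in the 10000-cell library, but with all libraries thinned to equal contacts between bins it called 0 (338 at unadjusted p under 0.05). Scores in that library lay above the 1000-cell mean at chromosome 13, 103.2 Mb, by 0.68, at chromosome 2, 75.92 Mb, by 0.63 and at chromosome 18, 41.12 Mb, by 0.60. Differences were -0.69 at chromosome 9, 17.48 Mb, -0.60 at chromosome 8, 145.72 Mb, and -0.58 at chromosome 7, 101.16 Mb. The 10 named in each direction spanned 0.53 to 0.68 and -0.50 to -0.69, and the 10000-cell library lay beyond both others at all of them. Without HEK293 1000-cell replicate 1 the difference at chromosome 9, 17.48 Mb, was -0.44. With the input that the protocol text gives, it called 0 (256 at unadjusted p under 0.05), where chromosome 9 at 17.48 Mb turned to 0.03. Equal depth gave 100 calls, reads without balancing 97, and leaving out HEK293 1000-cell replicate 1 or 2 gave 416 or 400.

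For compartment scores limma called 13 of 7016 bins, 7 higher and 6 lower in the 10000-cell library, and 0 at equal contacts between bins (209 at unadjusted p under 0.05). The difference was 2.17 at chromosome 9, 139.2 to 139.6 Mb, 1.22 at chromosome 5, 155.6 to 156 Mb, and 1.06 at chromosome 8, 6.8 to 7.2 Mb. It was -1.43 at chromosome 4, 4.4 to 4.8 Mb, -1.29 at chromosome X, 88.8 to 89.2 Mb, and -1.22 at chromosome 4, 11.6 to 12 Mb. The 13 spanned 0.93 to 2.17 and -0.93 to -1.43, and the 10000-cell library lay beyond both others in all. At equal depth limma called 0 bins (558 at unadjusted p under 0.05), and with the input of the protocol text it called 1. Leaving out HEK293T replicates 1 to 4 gave 75, 3, 69 and 4 calls, and leaving out HEK293 1000-cell replicate 1 or 2 gave 8 or 2.

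For relative coverage limma called 20 of 2816 bins, all higher in the 10000-cell library, with 1282 at unadjusted p under 0.05, and leaving out HEK293T replicate 2, 3 or 4 gave 0 calls (1027, 1070 and 1047 at unadjusted p under 0.05). The difference was 0.48 at chromosome 15, 20 to 21 Mb, 0.46 at chromosome 21, 9 to 10 Mb, and 0.43 in the strongest bin of chromosome 7, 62 to 64 Mb. At chromosome 21 it was 0.63 without HEK293 1000-cell replicate 1 and 0.29 without replicate 2. Those bins lie next to stretches without listed contacts that end at 20.04, 9.4 and 61.52 Mb. The 8 named regions spanned 0.37 to 0.48, and the 10000-cell library lay above both others in all. Without the trend on the compartment vector 10 bins were called and none of those 3 regions, whose differences were then 0.53, 0.48 and 0.48. A stricter bin filter gave 43, bins of 400 kb gave 82, and with the input of the protocol text limma called 0 (1290 at unadjusted p under 0.05). Leaving out HEK293 1000-cell replicate 1 or 2 gave 192 or 1.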

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

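The search for libraries standing apart covered 14 measures, of which the share of contacts within a bin, the compartment strength after background subtraction and the mitochondrial pairs were chosen after the data were seen.

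Boundary depth in HEK293T replicate 1 was -0.66, lower than in the other 3 HEK293T libraries by a gap of 0.861 of the group's range. Read pairs within the mitochondrial genome numbered 147 per 1000000 read pairs in HEK293T replicate 1, against 1050, 1076 and 1073 in the other 3 HEK293T libraries, a gap of 0.972 of the range. Dixon's test marks about 1 in 20 groups by chance. Pairs joining the mitochondrial genome, which lies outside the nucleus, to a nuclear chromosome played no part in the comparisons and stood far above the limit that a count of 0 allows, at most 0.154 per 1000000 read pairs, in all 7 libraries. They numbered 219, 717, 532 and 602 per 1000000 in HEK293T replicates 1 to 4. In HEK293 they numbered 284 and 197 per 1000000 from 1000 cells and 1228 per 1000000 from 10000 cells.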

How the results depend on the processing

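Removing the coverage trend, thinning to equal contacts between bins, the long-range share without contacts inside a bin, the gene-poor chromosomes without the pair 13 and 18 and subtracting the interchromosomal background were chosen after the data were seen. Of 130 alternatives to the main results 73 kept direction and side of the threshold, 43 moved a count by over 1.5 times or a value beyond its spread, 5 lost and 2 gained a call and 7 reversed. Of 289 for named regions 203 kept the call, 79 lost it and 7 reversed. The cause was not tested unless the construction shows it, as thinning leaves fewer reads and a stricter filter fewer bins. Compartment calls between lines were 406 at equal depth, 413 with a stricter filter and 32 at equal contacts. Between inputs they were 5 unbalanced, 80 with the stricter filter, 1 with the protocol's input, and 0 by limma at equal depth (558 at unadjusted p under 0.05), with each library's own eigenvector (1060) and at equal contacts (209). Boundary calls between lines were 2055 unbalanced (789 higher and 1266 lower in HEK293T, from 67 and 65), 40 at equal depth, 254 with 800 kb, 6 at equal contacts and 211 at matched input. Between inputs they were 97 unbalanced, 100 at equal depth, and 0 by limma at equal contacts (338 at unadjusted p under 0.05) and with the protocol's input (256). Coverage calls between lines were 3234 in 400 kb bins, 366 without the trend and 2413 with no minimum difference. Between inputs they were 43 with the stricter filter, 82 in 400 kb bins, 10 without the trend, 628 with no minimum and 0 by limma with the protocol's input (1290 at unadjusted p under 0.05). Pair calls were 426 unbalanced (357 higher and 69 lower, from 30 and 22), 28 with the stricter filter (27 and 1), 82 with a pseudocount of 1 (62 and 20), 17 with an expected value per chromosome pair (5 and 12) and 79 at matched input (31 and 48). Without balancing, named boundaries reversed at chromosome 1, 1.24 and 1.52 Mb (-0.43 and -0.57), chromosome 3, 49.72 Mb (-0.23), chromosome 21, 22.32 Mb (0.19), and chromosome 2, 213.44 and 156.16 Mb (0.11 and 0.27). With the protocol's input chromosome 9, 17.48 Mb, reversed (0.0274).

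Between lines, the intrachromosomal difference reversed to 2.65 percentage points without contacts inside a bin. The long-range difference reversed to -1.54 without those contacts and was 1.99 beyond 20 Mb (exact p = 0.0571) and 5.88 at matched input, where no p under 0.0667 can be had. The slope difference reversed to 0.0157 over 1 to 20 Mb and 0.0281 at matched input, and that of the small gene-rich chromosomes to -0.0035 without chromosome 21 and -0.031 at matched input. The gene-poor difference was -0.075 without the pair 13 and 18 (exact p = 0.0571). Without balancing the strength difference of -1.30 and the depth difference of -0.0262 reached an exact p of 0.0286, and the similarity difference at matched input was 0.0496. Between inputs, the intrachromosomal difference was -16.7 without contacts inside a bin, the long-range difference reversed to 7.01 without those contacts and was -0.798 beyond 20 Mb and -2.24 with the protocol's input. The slope difference was 0.0249 over 1 to 20 Mb, the strength difference -1.77 over the outer 10% and -0.807 with the protocol's input, and the depth difference 0.0408 with 800 kb and 0.0133 with the protocol's input. Only replicate numbers 1 and 2 occur in both lines and the labels name no shared batch, so they do not pair libraries. Deviations of libraries with the same number correlated at -0.01 and -0.01 for compartments, -0.01 and 0.00 for boundaries and 0.66 and 0.19 for coverage. With the replicate block the calls between lines were 13 compartment bins, 3 boundaries and 2 pairs, and the compartment calls between inputs 172. The long-range and similarity differences were 6.22 and 0.0585, with too few splits for a p under 0.05.

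Leaving out each library in turn (between inputs, each 1000-cell library) gave 558 to 756 compartment calls between lines (590, 608 and 558 without HEK293T replicates 2, 3 and 4) and 2 to 75 between inputs (75, 3, 69 and 4 without HEK293T replicates 1 to 4, 8 and 2 without HEK293 1000-cell replicates 1 and 2). Boundary calls were 12 to 211 between lines (24, 12, 19 and 14 without HEK293T replicates 1 to 4, 199 without HEK293 1000-cell replicate 2, 211 without the 10000-cell library) and 400 to 648 between inputs (416 and 400 without HEK293 1000-cell replicates 1 and 2). Coverage calls were 1116 to 1380 between lines and 0 to 192 between inputs, with 0 by limma without HEK293T replicates 2, 3 and 4 (1027, 1070 and 1047 at unadjusted p under 0.05), 192 without HEK293 1000-cell replicate 1 and 1 without replicate 2. Pair calls were 16 to 93 (25, 16 and 22 without HEK293T replicates 1, 2 and 4, 93 without HEK293 1000-cell replicate 2, 79 without the 10000-cell library). Differences between lines ran from -5.10 to -1.94 for the intrachromosomal share, 5.88 to 8.75 for the long-range share, -0.0213 to 0.0281 for the slope and -1.55 to -0.892 for strength. They ran from -0.0193 to -0.00655 for depth, -0.0307 to 0.0667 for the small gene-rich chromosomes and 0.0385 to 0.0946 for similarity. The slope and the small gene-rich chromosomes reversed without HEK293T replicate 1 (0.0271 and -0.00051) and without the 10000-cell library. That library also gave the ends at -5.10, 5.88, -1.55 and -0.00655. These designs cannot reach an exact p of 0.05. Differences between inputs ran from -6.30 to -4.12, -5.71 to -5.09, 0.086 to 0.0931, -1.31 to -1.0, 0.0241 to 0.0254 and -0.195 to -0.104 for the first 6 of these measures. Depth limits the maps most at 10000 cells, with 5845581 intrachromosomal pairs between bins.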

Other observations

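The scan for contacts raised in a single line, the tests of its splits, of its spread over bins and of the number of its ends with a large coverage step, the count of chromosomes by sign and the strength at equal contacts between bins were chosen after the results were seen. The splits of the 4 limma counts, the slopes by batch, the background subtraction and the median coverage steps were planned beforehand, but the bound for excluding a median step was widened by its spread afterwards.

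The 1000 pairs of bins with the strongest contact between chromosomes, chosen by their mean over the libraries of both lines, fell into 130 clusters, and 19 clusters of at least 5 pairs held 856 of them. The widest joined chromosome 13 at 62 to 86 Mb to chromosome 18 at 19 to 39 Mb over 230 pairs, with a peak of 8.62 ± 0.35 (SD, n = 4) in HEK293T and 8.26 ± 0.74 (SD, n = 3) in HEK293. Others joined chromosome 7 at 133 to 155 Mb to chromosome 18 at 27 to 38 Mb over 139 pairs and chromosome 1 at 66 to 80 Mb to chromosome 4 at 8 to 21 Mb over 112 pairs. Further ones joined chromosome 3 at 162 to 178 Mb to chromosome 10 at 18 to 28 Mb over 66 pairs and chromosome 8 at 35 to 42 Mb to chromosome X at 69 to 89 Mb over 57 pairs. At the peaks of the 19, the lowest log2 observed over expected in any library of either line was 2.19, in a cluster of chromosomes 1 and 4. No pair was called between lines by limma in 16 of the 19, a test with little power (8.96% of simulated shifts of 0.6 recovered), and the 27 called pairs in the other 3 were all higher in HEK293T. A candidate explanation is that these clusters mark rearrangements shared by the lines that also changed copy number. The median step of the shared coverage profile at 36 ends of 19 junctions was 0.47, against 0.19 at random positions. It lay at percentile 100 of 10000 random sets, whose 95th percentile was 0.26. Some ends lie within the 10 Mb window of the step, as on chromosome 18 at 27, 32, 34 and 38 Mb. They are not independent, so the percentile may be overstated. A chromosome break was not observed directly.

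Once the trend on compartments was removed, there were 18 runs of at least 5 called coverage bins, some of them made mostly by the removal. On chromosome 1 there were 7 runs lower in HEK293T, the deepest at 109 to 121 Mb with 0.22 ± 0.01 (SD, n = 4) in HEK293T and 0.80 ± 0.03 (SD, n = 3) in HEK293. Coverage was also lower in HEK293T on chromosome 8 at 126 to 141 Mb (-0.44, from -0.16 before removal, with 2 of 15 bins called then), on chromosome 10 at 106 to 114 Mb (-0.51, from -0.13, with 2 of 8) and 128 to 136 Mb (-0.47), and on chromosome 15 at 91 to 100 Mb (-0.49, with 4 of 8 called before). It was higher on chromosome 21 at 17 to 27 Mb (0.52), on chromosome 13 at 62 to 76 Mb (0.45) and 82 to 91 Mb (0.41), and on chromosome 17 at 0 to 10 Mb (0.41), where the difference before removal had the other sign (-0.0525) and 0 of 8 bins were called. The others were on chromosome 18 at 27 to 34 Mb (0.41), on chromosome 5 at 22 to 30 Mb (0.40) and on chromosome 14 at 27 to 37 Mb (0.37, with 3 of 7 bins called before removal). The run of chromosome 21 contains the compartment bin at 22.4 Mb and the boundary at 22.32 Mb that differed between the lines.

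Some contacts were raised in 1 line and not in the other. In 41 pairs of 1 Mb bins every library of a line had a log2 observed over expected of at least 3 and at least 10 reads while every library of the other stayed at 1 or below. They were 17 pairs in HEK293T and 24 in HEK293, forming 14 junctions, which need not be separate events. In HEK293T they joined chromosome 9 at 81 to 82 Mb to chromosome 18 at 77 to 78 Mb (806 read pairs, against 1 in HEK293) and chromosome 13 at 62 to 63 Mb to chromosome 18 at 77 to 78 Mb (723 against 3). They also joined chromosome 10 at 101 to 102 Mb to chromosome X at 78 to 79 Mb (315 against 3). In HEK293 they joined chromosome 1 at 108 to 109 Mb to chromosome 17 at 11 to 12 Mb (213 read pairs, against 9 in HEK293T), which lie at the edges of the coverage runs of chromosomes 1 and 17 above, the latter seen only once the trend was removed. They also joined chromosome 3 at 114 to 115 Mb to chromosome 6 at 29 to 30 Mb (148 against 8). Chromosome 3 at 86 to 87 Mb was joined to chromosome 20 at 11 to 12 Mb (111 against 5). In HEK293T the junctions of chromosomes 9 and 13 above share an interval of chromosome 18. Chromosome 9 at 82 to 83 Mb was itself joined to chromosome 13 at 62 to 63 Mb in both lines (8.1 in HEK293T and 7.9 in HEK293).

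For these pairs 1 of 35 splits, the real one, gave as many as 41 and the highest of the others gave 0. That cannot exclude chance, since the rule was chosen after the data were seen and 1 of 35 is the smallest share possible. Misplaced reads from a repeated sequence are argued against for 97.6% of the pairs, 40 of 41, which had at least 5 raised pairs around them. Their highest pair of 40 kb bins held under 5% of the reads in a window reaching 1 Mb beyond the pair on each side. Among a pair's own reads the share can be larger, as with 58 of 806 in HEK293T for the junction of chromosomes 9 and 18. Such misplaced reads may explain the remaining pair, of chromosome 1 at 196 to 197 Mb and chromosome 10 at 100 to 101 Mb in HEK293. It had 61 reads over all libraries in a single pair of 40 kb bins, 41.5% of those in the wider window, and 0 of 48 pairs around it raised. A candidate explanation for part of the junctions is a rearrangement that also changed copy number. Of 22 ends, 7 had a step above 0.264 in the coverage difference with the trend removed, at percentile 99.98 of random sets. Among them were both ends of the junction of chromosomes 1 and 17 (0.47 and 0.41). This count was chosen after the results were seen. Some ends also lie close together, as on chromosome 10 at 100 and 101 Mb, so the percentile may be overstated. For the ends as a whole such a change cannot be told apart from none. Their median step of 0.10 lay at percentile 89.2, within an SD (0.0196) of the 95th percentile of 0.11. Rearrangements without such a step, a biological difference between the lines, stay open and were not tested.

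The coverage difference between lines followed the compartments. Taken as each library's deviation from the midpoint of the 2 line means, which sets opposite signs for the lines, the slope of coverage on the compartment vector was -0.164, -0.187, -0.198 and -0.200 in HEK293T, and 0.187 and 0.119 in HEK293 from 1000 cells and 0.257 from 10000 cells. Copy number as its whole cause is argued against by a negative correlation across bins on 23 of 23 chromosomes, with a median of -0.849. A bias of digestion, ligation or base composition between batches cannot be told apart from a difference between the lines, since each batch holds a single group. The slopes of the HEK293 batches differed by 0.279 of the difference between lines, near the bound of 0.25 set for excluding it.

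Compartment strength was higher in HEK293 on average, with a difference, HEK293T minus HEK293, of -1.16 that did not pass its test. At equal contacts between bins the difference was -1.14, 0.98 of that at full depth. Random thinning hardly shifts means over many bin pairs, and the balancing factors stayed those of full depth. The test could therefore hardly have shown an effect of sequencing depth, which it does not exclude. Whether random ligation was the source cannot be told, as far as the mean interchromosomal contact measures it. After that contact was subtracted, HEK293 still exceeded HEK293T by 1.15 on average. That is less than 2 times the larger SD of 0.746, the bound set for excluding it, so the difference itself stays uncertain. The HEK293 range after subtraction, from 3.31 to 4.73, also overlapped that of HEK293T from 2.64 to 3.40. The ranges of the lines overlapped before subtraction too. A difference between the cell lines stays open and was not tested apart from batch.

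Other splits of the 7 libraries into 4 and 3 were tried for the limma counts. For compartment bins 1 of 35 splits gave as many calls as the real 943, with at most 0 in the others, and for boundaries 1 of 35 reached 132, with at most 0 in the others. For coverage 1 of 35 splits reached 1240, with at most 0 in the others, and for contacts between chromosomes 1 of 35 reached 52, with at most 5 in the others. The real split thus stood alone for all 4 counts, but 1 of 35 is the smallest share possible. Every other split also mixes the lines, which widens the spread within its groups and lowers its calls. Chance is therefore not excluded, and neither is batch, which follows the same split.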
